A study of Drosophila melanogaster with 3 samples.

How the data were processed

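RNA of single cells from the posterior midgut of adult progeny flies was measured in 3 libraries, each made from 30 pooled intestines: 1 control, 1 reprogrammed (mothers with a dominant-negative insulin receptor in the germline) and 1 rescued (such mothers fed methionine). Per the labels, midguts were dissected on ice, dissociated with trypsin and elastase, passed through a strainer and loaded on 10x Genomics droplets. Per the file headers, the authors counted molecules with Cell Ranger 5.0.1, and the deposited values are raw UMI counts per gene and cell barcode, with no normalization. The deposited barcodes are those called as cells, with a lowest total of 500 UMIs. The genome build and annotation behind the counts are not given in the sources used here. The files list 16727 genes by symbol, of which 12512 match a symbol of the RefSeq annotation of Release 6 directly and 3996 through a synonym, a match used only to find gene list members and neighbouring genes. They list 0 mitochondrial genes.

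Counts were read with Python 3.11.15, scanpy 1.11.5 and anndata 0.12.19, and analysed with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Cells with at least 200 genes were kept, which removed 175 control, 202 reprogrammed and 337 rescued barcodes. A planned limit on the share of mitochondrial UMIs could not be applied without mitochondrial genes. The automatic threshold of Scrublet, run per library through scanpy, called 0 doublets in each library, so the 5% of cells with the highest scores per library were removed instead (300, 287 and 301 cells), a choice made after seeing this. The kept cells held 60.1, 64.1 and 57.4 M UMIs (M, 10 to the power of 6), with a median of 6153, 7487 and 7286 UMIs and 1259, 1388 and 1348 genes per cell.

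Cells of the 3 libraries were clustered together: totals scaled, logarithm taken, 2000 variable genes chosen across libraries, 30 principal components, 15 neighbours, and the Leiden method at resolution 1.0, with no correction between libraries. This gave 22 clusters. A gene counted as raised in a cluster when its CPM was over 2 times the median cluster (with 5 CPM added to each) and over 20% of the cluster's cells held it. A cluster took the name of the class with the most raised markers out of 11 fixed marker lists. It stayed unnamed with under 3 raised markers, with more markers of another class among its 10 leading genes, with a larger share of another class's markers raised, or with low depth and none of its own markers among the leading genes. Shares of kept cells carry exact Clopper-Pearson 95% intervals.

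For each comparison, the UMI counts of all cells of a class were summed per library and divided by the class total to give CPM. Log2 ratios of CPM used a prior of 0.5 counts, and their 95% intervals are exact for counting (binomial, conditional on the sum of both libraries). These intervals treat each UMI of the summed counts as independent, so they do not cover differences between cells. They also cover neither differences between animals nor between preparations, because each group had 1 library. The class totals were 34.6, 43.7 and 40.43 M UMIs in progenitor-like, 10.47, 8.16 and 8.41 M in enterocyte-like and 2.23, 1.79 and 1.19 M in enteroendocrine-like cells of the control, reprogrammed and rescued libraries. Of 30 fixed gene lists, the median log2 ratio over members with at least 50 UMIs in both libraries together was taken and set against 10000 random lists of the same size, matched on expression in 20 bins (1000 lists under alternatives). The percentile describes these libraries and is no test.

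The distance between libraries is the root mean square log2 CPM ratio over genes with at least 100 UMIs, set beside the value that Poisson counts from a shared profile give over 100 simulations. For the return of genes in the rescued library, the 50 highest and 50 lowest genes of reprogrammed against control were chosen on one random part of the cells and measured on the other, over the cells of the rescued library as a whole. The share that remained is the median ratio over these genes, signed by the direction of selection, in the rescued library divided by that in the reprogrammed library. Its neutral value comes from 100 simulated sets of 3 libraries that deviate independently from one profile. Genes are named by a fixed rule. Per comparison and class, genes with at least 100 UMIs and at least 50 CPM in the higher library were ranked by the interval limit nearest to 0. Up to 8 highest and 8 lowest were named in enterocyte-like cells, and up to 5 and 5 in the other classes and in all kept cells. From each list described, up to 4 members with the most UMIs and the 2 with the largest absolute ratio were added, and InR, foxo, Thor, Sam-S, E(z), esg, Dl and pros always qualify.

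The ratios, intervals and list medians were run on simulated data for reprogrammed against control. Poisson counts were drawn from the control profile at each library's depth, with known ratios given to 200 genes. Such counts hold no spread between cells or libraries, so the intervals reach about their stated level by construction. The values below describe counting error only. Clustering, cluster names, doublet removal, distances and returns were not part of this simulation. Intervals lay off 0 in the right direction for 98.5% of genes given a 1.5-fold ratio in progenitor-like cells (6863 genes measured), 88.2% in enterocyte-like cells (5153) and 84.6% in enteroendocrine-like cells (3466), for 100.0%, 98.2% and 100.0% at 2-fold, and for 100.0% in each class at 4-fold. Intervals of genes given no ratio held the true value in 95.8%, 95.7% and 95.8%. List medians given a ratio stood at percentile 100.0 in each class, and lists given none at 72.6, 52.2 and 83.8.

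Alternatives were a filter of at least 500 genes per cell, no limit on genes per cell (with predicted doublets still removed), predicted doublets kept, Leiden resolutions 0.5 and 2.0, and stress genes and enzymes left out of the variable genes. For ratios, they were median-of-ratios scaling, a total without the 20 most abundant genes, the mean of CPM per cell, cells thinned to 1000 UMIs with shallower cells left out, and list members with at least 10 or at least 200 UMIs. Distances were also taken over genes with at least 1000 UMIs, and returns with 200 genes each way. With genes chosen on rescued against control the roles of the rescued and reprogrammed libraries are swapped. Added after seeing the data were shares among the 3 named midgut classes, one mix of clusters in every library (the mean over libraries of each cluster's share of the cells of the class), and a distance without enteroendocrine-like cells with over 100 Akh UMIs. Other classes than the 3 midgut classes were left out of the comparisons because their cells were few or lie outside the midgut epithelium. Figures were drawn with matplotlib 3.10.9.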

Results

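Single-cell RNA libraries were made with 10x Genomics droplets from the posterior midgut, the rear digestive part of the fly gut, of adult Drosophila melanogaster. In this assay each captured transcript carries a unique molecular identifier (UMI), so that a count is a number of molecules. There were 3 libraries, 1 per group, each made from 30 pooled intestines. The control flies were progeny of mothers that carried the germline driver MTD-GAL4 without a transgene, the reprogrammed flies were progeny of mothers in which that driver expressed a dominant-negative insulin receptor in the germline, and the rescued flies were progeny of such mothers that had been fed methionine. All mothers were mated to Oregon R males. With 1 library per group there were no replicates, so no test was made, each difference is one between these libraries, and every interval given covers counting error only. The control, reprogrammed and rescued libraries held 6177, 5946 and 6355 barcodes with 62824814, 67837525 and 60491504 UMIs, and the median barcode held 5836, 7082 and 6789 UMIs. After the removal of cells with few genes and of predicted doublets, 5702, 5457 and 5717 cells were kept. Genes are named by the symbols in the files; the genome build is not given in the sources used here, and no positions are printed.

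The insulin receptor gene InR is given first because the transgene was a form of it. The transgene acted in the mothers' germline, so InR in the progeny midgut does not check which library belongs to which group. InR stood at 153, 127 and 98.4 counts-per-million (CPM) units in progenitor-like cells of the control, reprogrammed and rescued libraries. It stood at 57.2, 54.4 and 21.5 CPM in enterocyte-like cells, and at 148, 309 and 175 CPM in enteroendocrine-like cells.

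Clusters were named from marker genes fixed before the data were examined. Progenitor-like cells, with the stem cell and enteroblast genes esg and Dl among their markers, made up 46.4% of the kept control cells (95% Clopper-Pearson interval 45.1 to 47.7, 2644 of 5702), 59.6% of the reprogrammed cells (58.3 to 60.9, 3251 of 5457) and 65.3% of the rescued cells (64.0 to 66.5, 3731 of 5717). Enterocyte-like cells, the absorptive cells that make digestive enzymes, made up 18.3% (17.35 to 19.37, 1046 of 5702), 12.9% (703 of 5457) and 15.4% (14.52 to 16.41). Enteroendocrine-like cells, the hormone-secreting cells, made up 12.1% (11.2 to 12.9), 12.8% (11.9 to 13.7) and 8.15% (7.45 to 8.89). Visceral muscle-like cells made up 4.68%, 3.79% and 1.87%, and hemocyte-like cells 0.32%, 0.46% and 0.75% (0.74% and 0.81% in the control and reprogrammed libraries at Leiden resolution 0.5). Cells with Malpighian tubule and hindgut markers, which lie outside the midgut, were 3.44% of the control cells (2.98 to 3.94), 0.86% of the reprogrammed cells (0.63 to 1.14) and 0.21% of the rescued cells (0.11 to 0.37). This class was 1.56%, 0.27% and 0.05% at Leiden resolution 2.0, and 1.77%, 0.50% and 0.02% with at least 500 genes. With no filter on genes per cell it was unnamed. Its rescued cells may be of another type, as that library held 4 and 0 UMIs of its leading genes CG14245 and Muc11A. Clusters left without a name held 14.8%, 9.68% and 8.31% of the cells, and 6.49%, 6.98% and 5.93% at Leiden resolution 0.5. One of them, with 315, 107 and 83 cells, combined raised progenitor markers with digestive enzyme genes at low depth. Among the 3 named midgut classes alone, a denominator chosen after seeing the data, the progenitor-like share was 60.4%, 69.9% and 73.4%. The thresholds for naming clusters were also set after the data were seen.

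**Figure D1:**
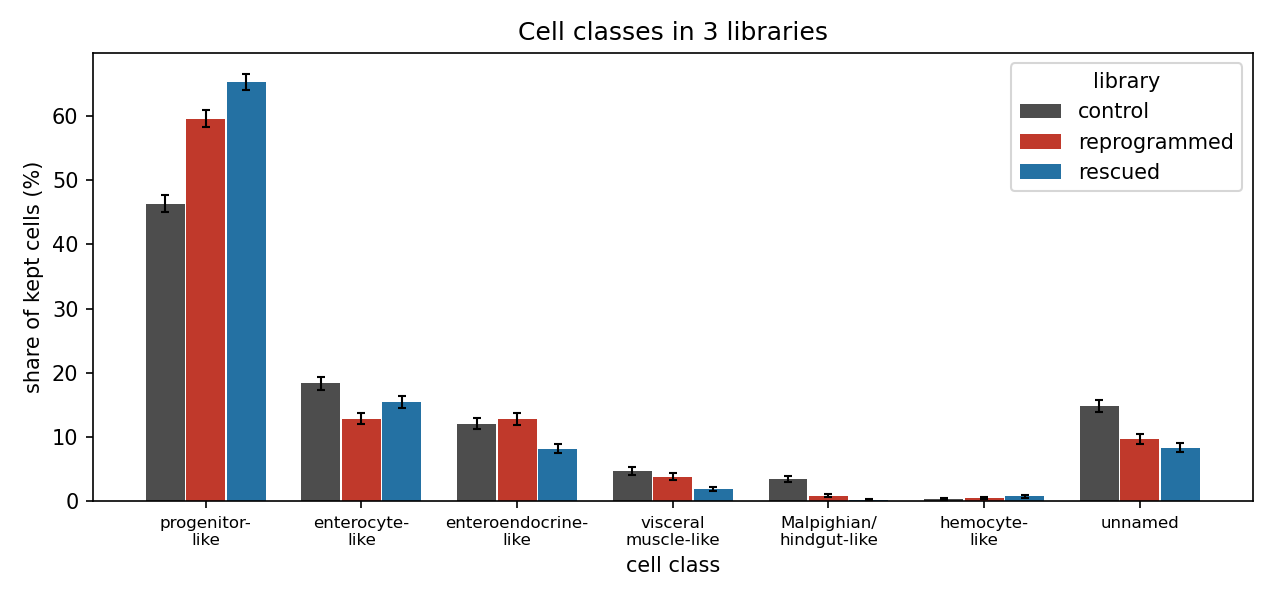
Bars show the share of kept cells (%) in each cell class for the control, reprogrammed and rescued libraries, with exact 95% binomial intervals as error bars that cover counting error only. The progenitor-like bars stand at 46.4%, 59.6% and 65.3%, and the enteroendocrine-like bars at 12.1%, 12.8% and 8.15%.

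Cluster 0 was the largest cluster of the progenitor-like class in the control and rescued libraries (36.2% and 39.5% of the class), and cluster 1 in the reprogrammed library (32.7%). Cluster 0 held 26.1% there, and cluster 1 held 22.3% and 38.7% in the control and rescued libraries. Cluster 3, with the replication clamp gene PCNA and nucleolar genes among its leading genes, held 17.8%, 22.2% and 10.9% of the class. In the enterocyte-like class cluster 4 was the largest in every library (47.6%, 48.2% and 47.7%), cluster 9 held 27.2%, 14.9% and 13.8%, cluster 6 held 17.3%, 19.1% and 32.2%, and cluster 14 held 7.9%, 17.8% and 6.3%. Median depth was 3250, 5721 and 5440 UMIs in enterocyte-like cells, 10112, 9856 and 8522 in progenitor-like cells and 2314, 1699 and 1672 in enteroendocrine-like cells.

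The first comparison asks how the midgut of progeny of mothers with a blocked germline insulin receptor differed from that of control progeny. CG32368 and CG31324 had the highest ratios in progenitor-like cells and were higher in all 3 classes. CG32368 stood at 84.0 against 11.2 CPM in progenitor-like cells (log2 ratio 2.90, interval 2.75 to 3.06), at 158 against 29.7 in enterocyte-like cells (2.41, 2.24 to 2.60) and at 73.0 against 19.8 in enteroendocrine-like cells (1.87, 1.38 to 2.41). CG31324 stood at 122 against 18.9 (2.69, 2.57 to 2.81), 61.9 against 8.2 (2.91, 2.58 to 3.26) and 141 against 28.3 CPM (2.31, 1.91 to 2.74). Heat shock genes were lower in progenitor-like and enteroendocrine-like cells, and genes for cell division and for the proteasome, the protease complex that degrades tagged proteins, were higher in enterocyte-like cells.

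Of the heat shock genes, 13 of 15 measured members were lower in progenitor-like cells (list median -0.43) and 12 of 12 in enteroendocrine-like cells (-0.56), both below all 10000 random lists of matched expression, a percentile that describes these libraries. The small heat shock gene Hsp26 stood at 3291 against 5450.1 CPM in progenitor-like cells (-0.73, -0.74 to -0.72), Hsp23 at 868 against 1971 (-1.18, -1.20 to -1.17) and Hsp27 at 1141 against 2081 (-0.87, -0.88 to -0.85). In enteroendocrine-like cells Hsp26 stood at 4704 against 7037 CPM (-0.58, -0.62 to -0.54). The enterocyte-like median was -0.19 with 7 of 11 lower, and it lay between -0.04, when each cell was weighted equally, and -0.56, among cells with at least 500 genes, over the alternatives. Nuclear-encoded genes of respiratory complexes II to V were lower by small amounts, 31 of 33 in progenitor-like cells (median -0.10) and 29 of 33 in enteroendocrine-like cells (-0.13), both below all random lists. CG1746, which encodes the c subunit of ATP synthase, stood at 2808 against 3070.0 CPM in progenitor-like cells (-0.13, -0.14 to -0.12). In enterocyte-like cells 19 of 33 were lower (-0.06, percentile 3.57, and -0.25 with median-of-ratios scaling). With one mix of clusters in every library, an alternative chosen after seeing the data, the progenitor-like median was -0.19, and among cells with at least 500 genes the enteroendocrine-like median was -0.07. Complex I genes had medians of -0.09, 0.06 and -0.12 in progenitor-like, enterocyte-like and enteroendocrine-like cells, and tricarboxylic acid cycle genes -0.11, 0.04 and -0.11. The enterocyte-like values were -0.14 and -0.15 with median-of-ratios scaling. Glycolysis genes were higher in progenitor-like cells (11 of 12, median 0.12, percentile 98.1, and 0.08 with one mix of clusters), such as Tpi at 334 against 267 CPM and Pglym78 at 212 against 161 CPM, and had medians of 0.00 and -0.09 in enterocyte-like and enteroendocrine-like cells, the former being -0.19 with median-of-ratios scaling.

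In enterocyte-like cells the median ratio over all measured genes was 0.20, and 0.01 with median-of-ratios scaling, so list values there are given beside that shift. All 31 measured proteasome genes were higher (median 0.36, percentile 99.8, and 0.17 with median-of-ratios scaling), with Prosbeta4 at 356 against 258 CPM (0.47, 0.39 to 0.55). All 15 measured cell cycle genes were higher (0.86, above all random lists), at low levels: PCNA stood at 43.4 against 18.5 CPM (1.23, 0.97 to 1.49) and the Cdc25 phosphatase gene stg at 9.4 against 2.9 (1.71, 1.09 to 2.38). The cell cycle median was 0.34 among cells with at least 500 genes, 0.48 with one mix of clusters and 0.56 with predicted doublets kept. All 6 measured Notch pathway genes were higher (0.88, percentile 99.9), with klu at 29.7 against 13.6 CPM (1.13, 0.82 to 1.44). The gene klu is also a progenitor marker used to name clusters, and how much progenitor RNA adds to these counts was not measured. The progenitor marker esg stood at 52.1 against 26.4 CPM in the same cells and at 382 against 337 CPM in progenitor-like cells. Genes for carbohydrate-digesting enzymes and lysozymes were lower (17 of 23, median -0.63, below all random lists, and between -0.33 and -0.37 with cells weighted equally, thinned to 1000 UMIs or in one mix of clusters), with the amylase gene Amy-p at 1186 against 2753 CPM (-1.22, -1.25 to -1.18), LysE at 395 against 1122 CPM (-1.51, -1.56 to -1.45) and Amyrel at 15.3 against 66.0 (-2.10, -2.39 to -1.83). Of the vacuolar proton pump genes 17 of 18 were lower (-0.32, percentile 0.01), with Vha16-1 at 1522 against 2090.4 CPM (-0.46, -0.49 to -0.43). Glutathione S-transferase and other redox genes were lower in 25 of 33 (-0.26, between -0.17 and -0.45 over the alternatives). GstE3 stood at 330 against 1479 CPM (-2.16, -2.22 to -2.11). CG13813 stood at 27.1 against 256 CPM (-3.24, -3.44 to -3.04). Thor, the translational repressor 4E-BP, stood at 586 against 1585 (-1.44, -1.48 to -1.39). Higher single genes were CG8083 at 99.1 against 10.4 CPM (3.25, 2.96 to 3.55), CG15199 at 95.3 against 12.9 (2.88, 2.62 to 3.16), the forkhead gene CHES-1-like at 134 against 27.8 (2.27, 2.08 to 2.46), and Try29F at 320.3 against 56.4 (2.504, 2.376 to 2.636), which is also a leading gene of cluster 14. Amy-p and Amy-d, the Lys genes, alphaTry and betaTry, and the Hsp70 genes are families of near-identical copies, between which the authors' counting could have split molecules.

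Digestive enzyme genes were also lower in the other classes, and how much free RNA adds to their counts there was not measured. In progenitor-like cells Jon25Biii, a serine protease gene, stood at 9.8 against 80.6 CPM and LysD at 10.0 against 61.9 CPM, and in enteroendocrine-like cells Jon25Biii stood at 29.5 against 377 CPM. Digestive protease list medians were -1.64 (22 of 22 lower, and -0.88 with predicted doublets kept) and -1.39 (17 of 17 lower) in these classes, and the carbohydrase list medians -1.82 and -2.23, the latter being 0.090 over members with at least 200 UMIs. Digestive enzymes together took 0.068%, 0.020% and 0.023% of the UMIs of control, reprogrammed and rescued progenitor-like cells, 0.437%, 0.184% and 0.226% in enteroendocrine-like cells, and 13.995%, 13.572% and 16.634% in enterocyte-like cells, where the protease median was -0.04. Among enteroendocrine-like cells InR was higher (309 against 148 CPM, 1.06, 0.87 to 1.27), as were foxo (122 against 74.1) and the hormone response gene Kr-h1 (83.0 against 25.6, 1.69, 1.25 to 2.16). The peptide hormone list had a median of 0.14 there (10 of 15 higher, percentile 99.1, and -0.23 with predicted doublets kept), with NPF at 17409 against 12866 CPM (0.44, 0.41 to 0.46), CG13565 at 52034 against 45406 CPM and AstC at 20109 against 26568 (-0.40, -0.42 to -0.38). Septate junction genes were higher in 9 of 10 (0.29), and -0.08 with predicted doublets kept. Genes of methionine and S-adenosylmethionine metabolism had medians of 0.05, 0.22 and 0.00 in progenitor-like, enterocyte-like and enteroendocrine-like cells, at percentiles 77.6, 53.6 and 41.8, the last median being -0.02 with median-of-ratios scaling. Within that list the S-adenosylmethionine synthetase gene Sam-S stood at 152 against 127 CPM in progenitor-like cells (0.25, 0.20 to 0.31) and CG10621 at 18.1 against 108 in enterocyte-like cells (-2.57, -2.83 to -2.33). Insulin, TOR and FOXO pathway genes had medians of -0.01, 0.10 and 0.10 at percentiles 32.8, 13.2 and 83.2, the enterocyte-like value being -0.09 with median-of-ratios scaling. Polycomb group genes had medians of 0.05, 0.36 and -0.14 at percentiles 77.9, 71.4 and 12.8. The histone methyltransferase gene E(z) had a log2 ratio of -0.04 in progenitor-like cells (-0.20 to 0.13). Ribosomal protein genes had medians of 0.02, 0.12 and 0.07, the enterocyte-like value being -0.08 with median-of-ratios scaling and also below 0 with predicted doublets kept, among cells with at least 500 genes and with one mix of clusters.

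**Figure D2:**
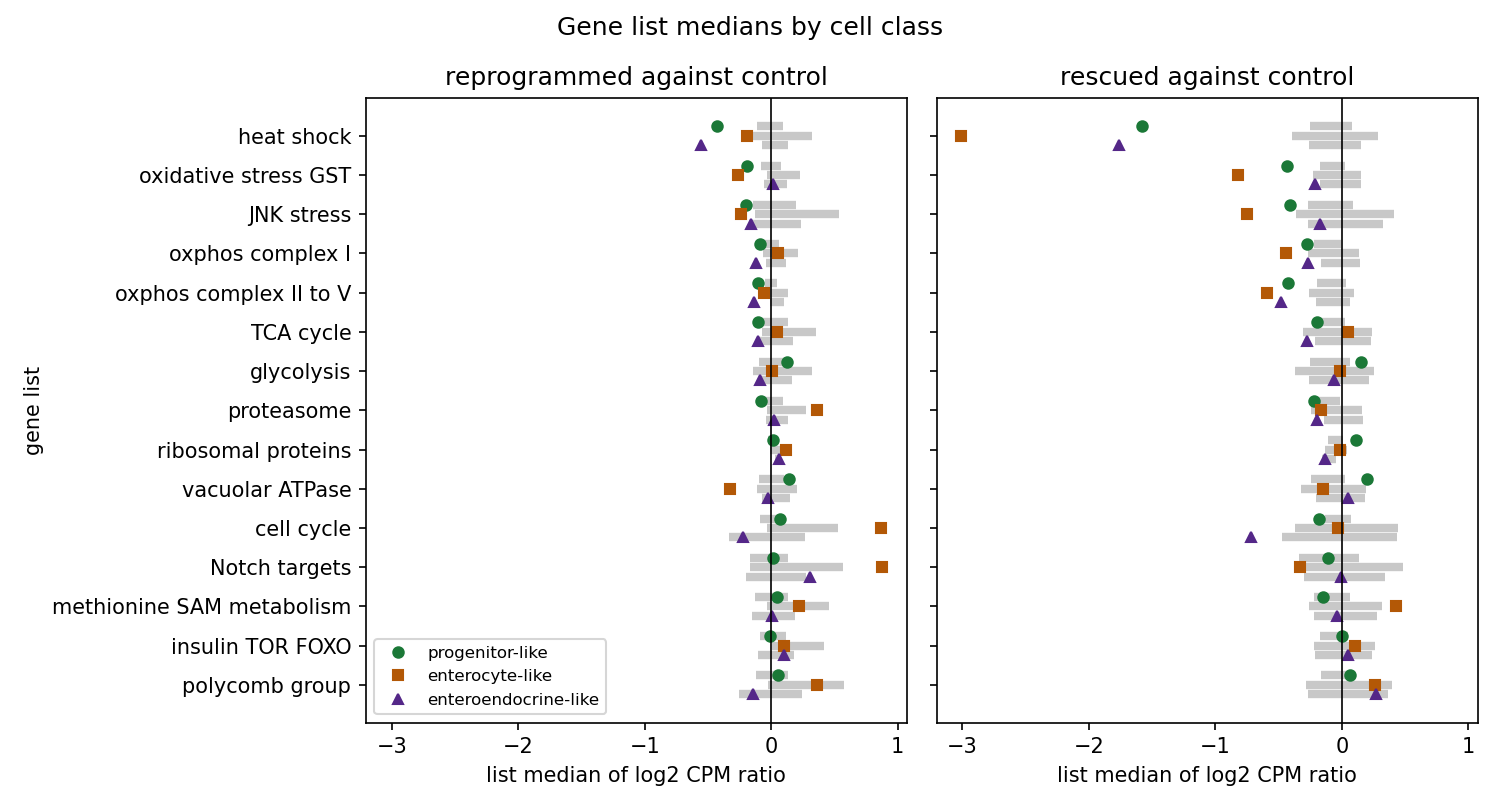
Each point is the median log2 CPM ratio of a gene list in progenitor-like (circles), enterocyte-like (squares) or enteroendocrine-like (triangles) cells, for reprogrammed against control and rescued against control, and grey bars span the central 95% of 10000 random lists of matched expression. The heat shock medians of rescued against control lie at -1.58, -3.01 and -1.77, left of their bars.

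The comparison of rescued with reprogrammed progeny asks what differed when the stressed mothers had been fed methionine. Heat shock genes were lower in the rescued library in all 3 classes, and respiratory chain genes were lower as well. Hsp26 stood at 679.6 against 3291 CPM in progenitor-like cells (-2.28, -2.29 to -2.26), at 105 against 1212 in enterocyte-like cells (-3.54, -3.64 to -3.44) and at 1052 against 4704 in enteroendocrine-like cells (-2.16, -2.25 to -2.07). CG32368, which was higher in the reprogrammed library, stood at 10.5 against 84.0 CPM in progenitor-like cells (-2.997, -3.147 to -2.853), near its control level of 11.2. In enterocyte-like cells carbohydrase genes were higher and proteasome, cell cycle and Notch pathway genes lower.

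List medians for heat shock were -1.22 in progenitor-like (13 of 14 lower), -2.27 in enterocyte-like (10 of 11) and -1.10 in enteroendocrine-like cells (11 of 12), all below all random lists. The enterocyte-like median was -1.47 over members with at least 200 UMIs, -1.59 with each cell thinned to 1000 UMIs and -1.89 with one mix of clusters in every library. The constitutive chaperone gene Hsc70-4 was the member that was higher in each class, for instance at 1814 against 1483 CPM in progenitor-like cells (0.29, 0.28 to 0.31). Complexes II to V were lower in 33 of 33 members in each class, with medians of -0.32, -0.60 and -0.30, where the medians over all genes were -0.06, -0.20 and -0.02. With one mix of clusters the progenitor-like value was -0.14, and with cells thinned to 1000 UMIs the enteroendocrine-like value was -0.17. Cytochrome c oxidase genes such as cype, at 785 against 1276 CPM in enterocyte-like cells (-0.70, -0.75 to -0.66), were among them. In enterocyte-like cells 21 of 22 carbohydrase and lysozyme genes were higher (1.01, above all random lists), with the maltase gene Mal-A1 at 4397 against 2105 CPM (1.06, 1.04 to 1.09) and the alpha-mannosidase genes CG9468 at 2976 against 686 (2.12, 2.07 to 2.16) and CG9463 at 313 against 42.2 (2.89, 2.73 to 3.06). CG9466 and CG9468 are leading genes of cluster 6, which held more of the rescued class. The scavenger receptor gene ninaD, for carotenoid uptake, stood at 156 against 11.3 CPM (3.78, 3.48 to 4.11). Proteasome genes were lower in 31 of 31 (-0.56, and -0.37 with median-of-ratios scaling), Notch pathway genes in 6 of 6 (-1.04), cell cycle genes in 12 of 14 (-0.83, and -0.23 with one mix of clusters) and redox genes in 30 of 33 (-0.62), with GstD2 at 13.9 against 162 CPM (-3.54, -3.83 to -3.27). InR stood at 21.5 against 54.4 CPM (-1.34, -1.60 to -1.09) and Thor at 997 against 586 (0.77, 0.72 to 0.82).

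In progenitor-like cells stg was lower, at 20.2 against 61.7 CPM (-1.61, -1.72 to -1.49), and 25 of 28 cell cycle genes were lower (-0.22), a median that was 0.03 with one mix of clusters. Sema-5c stood at 55.6 against 27.4 CPM (1.02, 0.92 to 1.12), Arc1, a gene for a capsid-forming protein, with 4011 against 2187 UMIs (0.99, 0.91 to 1.06), and mira, an adaptor for asymmetric division and a leading gene of clusters 0 and 1, at 460.2 against 281 (0.71, 0.68 to 0.74). Methionine metabolism genes had medians of -0.11, 0.06 and 0.06 at percentiles 36.0, 94.8 and 71.0, and Sam-S stood at 138 against 152 CPM in progenitor-like cells (-0.14, -0.19 to -0.09). Among the peptide hormone list the median was 0.10 in enteroendocrine-like cells (8 of 14 higher, and -0.11 when each cell was weighted equally, -0.12 among cells with at least 500 genes and -0.01 with one mix of clusters). Genes held by 2 cells gave the largest ratios of that class: Akh, the adipokinetic hormone gene, had 21674 UMIs in the rescued library, of which 99.7% were in 2 cells of cluster 11, and 9 in the reprogrammed and 11 in the control library. CG14075 had 11291 UMIs in the rescued library, 99.8% of them in 2 cells, and 0 in the others. The gene ImpL2, which encodes a secreted insulin-binding protein, had 2381 UMIs there, 74.9% in 2 cells, with 1061 in the reprogrammed and 1210 in the control library. Whether the 2 Akh cells belong to the midgut or to tissue carried along was not settled, which limits these values and the enteroendocrine-like distance given below.

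**Figure D3:**
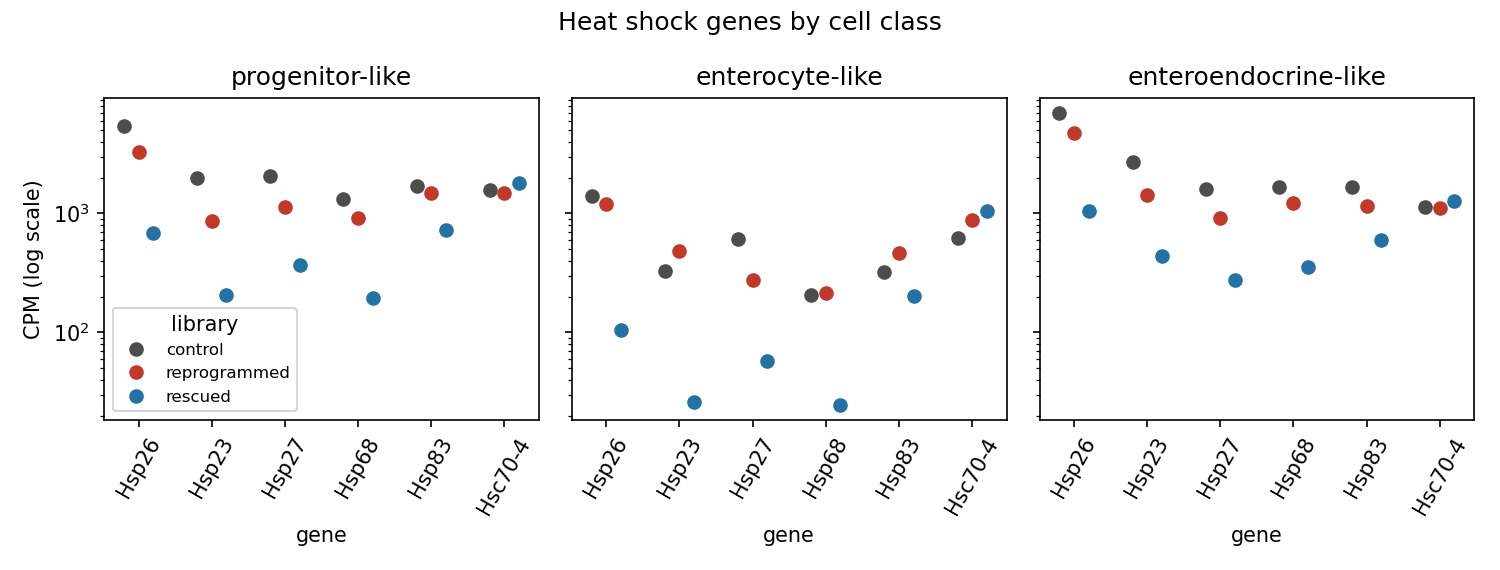
Points show the CPM (log scale) of 6 heat shock and chaperone genes in the summed counts of progenitor-like, enterocyte-like and enteroendocrine-like cells of the control, reprogrammed and rescued libraries. Hsp26 stands at 5450.1, 3291 and 679.6 CPM in progenitor-like cells, and Hsc70-4 at 1561, 1483 and 1814 CPM.

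The comparison of rescued with control progeny asks how close the rescued midgut lay to the control. Heat shock genes stood far apart, with medians of -1.58 in progenitor-like, -3.01 in enterocyte-like and -1.77 in enteroendocrine-like cells. Digestive proteases stood at -1.62, 0.27 and -1.51 (the last -0.71 with predicted doublets kept). Hsp26 stood at 679.6 against 5450.1 CPM (-3.003, -3.022 to -2.985), 105 against 1388 (-3.73, -3.83 to -3.63) and 1052 against 7037 (-2.74, -2.83 to -2.66). Respiratory complexes II to V were lower in 33 of 33, 33 of 33 and 32 of 33 members (-0.43, -0.60 and -0.48, the last being -0.31 with each cell thinned to 1000 UMIs). Complex I genes were lower in 32 of 32, 32 of 32 and 29 of 32 (-0.28, -0.44 and -0.27, the last being -0.17 with predicted doublets kept). CoVIII, a cytochrome c oxidase gene, stood at 430 against 666 CPM in progenitor-like cells (-0.63, -0.66 to -0.61) and 728 against 1339 in enterocyte-like cells (-0.88, -0.92 to -0.84). Proteasome medians were -0.22, -0.16 and -0.20 (29 of 32, 28 of 31 and 29 of 31 lower). With one mix of clusters in every library the progenitor-like values were -0.091 for the proteasome and -0.18 for complex I. Under at least 500 genes per cell the other proteasome medians were -0.095 and -0.096. In progenitor-like cells Arc1 was higher, at 99.2 against 21.7 CPM (2.19, 2.08 to 2.31), as was the kinesin gene unc-104 at 210 against 60.2 (1.80, 1.73 to 1.87). CG31324 stood at 56.3 against 18.9 CPM (1.57, 1.45 to 1.70) and at 122 in the reprogrammed library.

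Redox genes were lower in 32 of 34 members in progenitor-like cells (-0.44) and 30 of 33 in enterocyte-like cells (-0.82), and 22 of 29 in enteroendocrine-like cells (-0.21). GstD1 stood at 913 against 2313 CPM in enterocyte-like cells (-1.34, -1.38 to -1.30) and GstE3 at 212 against 1479 (-2.80, -2.87 to -2.73). Stress genes of the JNK pathway were lower in 8 of 9, 9 of 9 and 6 of 8 members (-0.41, -0.75 and -0.17, the last being -0.07 over members with at least 200 UMIs). The cytochrome P450 gene Cyp6a8 stood at 0.6 against 51.4 CPM in enterocyte-like cells (-6.30, -8.06 to -5.20) and CG13813 at 8.0 against 256 (-4.995, -5.378 to -4.656). Genes higher in enterocyte-like cells were CG8083 (179 against 10.4 CPM, 4.10, 3.82 to 4.40), ninaD (156 against 24.1, log2 ratio 2.69) and the amino acid transporter gene slif (90.1 against 16.1, 2.48, 2.24 to 2.73), and the first and last of these were also higher in the reprogrammed library, at 99.1 and 80.5 CPM. Carbohydrase and lysozyme genes were higher in 14 of 23 (0.82, above all random lists, and 0.40 with one mix of clusters) and digestive protease genes in 15 of 28 (0.27, and 0.00 when each cell was weighted equally), with betaTry at 28691 against 17472 CPM (0.72, 0.71 to 0.72). The methionine metabolism list had a median of 0.43 in enterocyte-like cells (11 of 15 higher, percentile 99.6), which was -0.08 when cells were thinned to 1000 UMIs, and -0.15 and -0.04 in progenitor-like and enteroendocrine-like cells, the last being 0.03 without the 20 most abundant genes in the total. Sam-S stood at 54.1 against 26.0 CPM in enterocyte-like cells (1.06, 0.84 to 1.28) and the adenosylhomocysteinase gene Ahcy13 at 115 against 63.9 (0.85, 0.71 to 0.99). Insulin, TOR and FOXO genes had medians of 0.00, 0.10 and 0.05 at percentiles 87.1, 76.6 and 65.8, and Polycomb group genes of 0.06, 0.27 and 0.27 at percentiles 94.2, 88.5 and 91.9.

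Over each class the rescued profile lay further from the control profile than the reprogrammed profile did. The root mean square log2 difference from the control was 0.43 for the reprogrammed and 0.53 for the rescued library in progenitor-like cells (7014 genes), 0.55 and 0.69 in enterocyte-like cells (5930 genes) and 0.43 and 0.59 in enteroendocrine-like cells (4049 genes), where counting error alone gives 0.12 and 0.12, 0.18 and 0.18, and 0.21 and 0.24. Without the 2 enteroendocrine-like cells that held over 100 Akh UMIs, a choice made after seeing the data, the last pair was 0.42 and 0.47 (ratio 1.10). The ratio of the distances was 1.23, 1.25 and 1.39 in the 3 classes, and in enteroendocrine-like cells 0.87 with predicted doublets kept and 3.49 over genes with at least 1000 UMIs, or 1.68 over such genes without the 2 Akh cells. The 50 highest and 50 lowest genes of reprogrammed against control were chosen on one random part of the cells and measured on the other. In progenitor-like cells the higher ones had a median log2 ratio to control of 0.70 in the reprogrammed and 0.27 in the rescued library, and the lower ones -0.67 and -0.60. In enterocyte-like cells these values were 1.16 and 0.88, and -1.03 and -0.92, and in enteroendocrine-like cells 0.17 and 0.08, and -0.84 and -1.11. The share that remained in the rescued library, which is its signed median over all 100 genes divided by that of the reprogrammed library, was 58.9%, 79.2% and 75.8%. It can differ from the medians of the higher and lower genes taken apart. Of the 100 genes, 40, 36 and 37 lay nearer to control than to reprogrammed, where simulated libraries that shared only the control gave 49.9, 50.4 and 50.2. Simulated libraries that differed at random from one another, and so shared only the control, gave means of 51.6%, 50.8% and 51.4%, and the central 95% of them spanned up to 62.3%, 61.0% and 62.4%. The enterocyte-like share was 57.4% with each cell thinned to 1000 UMIs, which lies inside the simulated span, 112% with predicted doublets kept and 121% among cells with at least 500 genes. The enteroendocrine-like share was 111% with each cell thinned to 1000 UMIs and 32.8% with predicted doublets kept. With genes chosen on rescued against control instead, the reprogrammed library had 49.1%, 29.3% and 50.6% of the rescued ratio, which is another quantity.

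Over all kept cells many of the genes with large ratios were held by few cells, several of them leading genes of small clusters outside the 3 classes, while CG14075 and Akh, given above, were held by enteroendocrine-like cells. The yolk protein genes Yp1, Yp2 and Yp3 had 8948, 8367 and 10060 UMIs in the control library, of which 88.7%, 83.6% and 86.0% were in 2 cells, against 1, 2 and 40 in the reprogrammed and 34, 26 and 101 in the rescued library; they lead unnamed cluster 20. PPO1 and PPO2, prophenoloxidase genes of crystal cells, had 13 and 16 UMIs in the control library, 4038 and 5840 in the reprogrammed and 2769 and 3071 in the rescued library, where 8 and 5 cells held over 100 UMIs of each. CG14125, the leading gene of unnamed cluster 21, had 1797, 39853 and 9366 UMIs in the control, reprogrammed and rescued libraries, of which 10 cells held 94.7%, 99.4% and 99.1%. CG1124 and to, leading genes of unnamed cluster 16, had 606, 7877 and 66 UMIs and 1017, 9475 and 979 UMIs. CG14245 and Muc11A, leading genes of the cluster with Malpighian tubule and hindgut markers, had 27930, 3873 and 4 UMIs and 10749, 1310 and 0 UMIs. CG1678, whose top cell lay in that cluster too, had 34689 UMIs in the rescued library, 1 in the control and 0 in the reprogrammed library.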

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

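The difference between classes was not tested for any list below, and all tests below were chosen after the results were seen, except the heat shock median in visceral muscle-like cells and the tests on neighbouring genes. For free RNA of heat shock genes, the limit on the lowest class of each gene was added after the value of 1.29 was seen.

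Some gene lists lay outside the central 95% of random lists with opposite directions in different classes under 1 comparison. For reprogrammed against control, the peptide hormone list had medians of 0.676 in progenitor-like, -0.144 in enterocyte-like and 0.14 in enteroendocrine-like cells, the proteasome list -0.083 in progenitor-like and 0.363 in enterocyte-like cells, and the proton pump list 0.137 in progenitor-like and -0.323 in enterocyte-like cells. The peptide hormone directions did not hold under all settings: the progenitor-like median was -0.125 under at least 500 genes per cell, the enterocyte-like median was 0.45 with mean of CPM per cell, 0.39 with each cell thinned to 1000 UMIs and 0.056 with one mix of clusters in every library, and the enteroendocrine-like median was -0.23 with predicted doublets kept. How much free RNA adds to peptide hormone counts outside the enteroendocrine-like class was not measured. The directions of the proteasome and proton pump medians held under every alternative tried. For rescued against control, carbohydrases and lysozymes stood at -1.05, 0.818 and -1.348, and digestive proteases at -1.619, 0.267 and -1.506, in progenitor-like, enterocyte-like and enteroendocrine-like cells. The enteroendocrine-like carbohydrase median was 0.295 over members with at least 200 UMIs, -0.265 with cells thinned and -0.208 with predicted doublets kept, and the enterocyte-like protease median was 0.003 with mean of CPM per cell and 0.040 with cells thinned. For rescued against reprogrammed, peptide hormones stood at -1.117 in progenitor-like and 0.098 in enteroendocrine-like cells, the latter being -0.108 with mean of CPM per cell, -0.116 under at least 500 genes per cell and -0.014 with one mix of clusters in every library. Digestive enzymes took 0.068% of control progenitor-like UMIs and 13.995% of control enterocyte-like UMIs.

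Heat shock genes were lowest in the rescued library in each of the 3 classes, and a different mix of clusters within the classes is unlikely as the whole cause, since with one mix of clusters in every library the median nearest to 0 was still -1.708 for rescued against control. Free RNA from 1 source, which adds alike to every droplet, is unlikely as the main source in progenitor-like cells. They held 7.27 times the heat shock UMIs per control cell of the lowest class (11.21 times the lowest class of each gene). Free RNA and the cells' own transcripts cannot be told apart in enterocyte-like (1.29 and 1.99 times) and enteroendocrine-like cells (2.09 and 3.22 times). The same holds for visceral muscle-like cells (33.19 UMIs against 29.01 in the lowest class). A handling or dissociation difference between the preparations may contribute. The muscle-like cells, which are not epithelial, had a median of -1.101 for rescued against control (7 of 10 lower). For rescued against reprogrammed it was -1.706 (9 of 10 lower). Since free RNA stays open there, these values are no separate evidence of handling. Other values of non-epithelial cells go both ways: the muscle-like cells had a median of 0.611 for reprogrammed against control, and the list took 0.666%, 0.809% and 0.867% of their UMIs in the control, reprogrammed and rescued libraries, while in the few hemocyte-like cells Hsp26 stood at 2960.2, 1669.6 and 866.7 CPM and the list took 1.132%, 0.76% and 0.666%, in the order of the progenitor-like cells. The maternal treatment stays open beside handling, since with 1 preparation per group these are confounded.

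Progenitor-like cells took a larger share in the reprogrammed and rescued libraries than in the control. For the rescued library a loss of enterocytes alone is unlikely, because the ratio of progenitor-like to enteroendocrine-like cells was 2.08 times that of the control library (1.83 to 2.37), and so are the filter and cells of other tissues as whole causes, as the share still exceeded the control share by 13.88 percentage points without a filter on genes per cell and by 13.05 among the 3 midgut classes. For the reprogrammed library that ratio was 1.22 times the control value (1.08 to 1.37), between the limits set. There a loss of enterocytes alone and a difference in the cells themselves cannot be told apart. The excess was 9.77 and 9.52 percentage points, also between the limits set. Without a filter on genes per cell the share was 60.01% (58.72 to 61.29) against 50.24% in the control (48.95 to 51.53). Among the 3 midgut classes it was 69.91% (68.57 to 71.23) against 60.39% (58.93 to 61.85). These counting intervals lie apart, which argues against the filter and cells of other tissues as whole causes, but not as partial ones. A difference in how well each class survived dissociation was not tested, and neither was a biological effect of the mothers' treatment. Both stay open.

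CG31324 and CG32368 were highest in the reprogrammed library in all 3 classes. Free RNA from 1 source is unlikely for both genes in all 3 classes together, as their CPM ratio in that library differed 4.94-fold between classes. For either gene or class alone it stays open. A regional difference, such as a stretch of chromosome from another strain, is unlikely for CG32368 if it spans its neighbours, since the 5 measured genes on either side had a median absolute log2 ratio of 0.13, at percentile 35.4 of 6708 such windows. For CG31324 the neighbours' median was 0.234, at percentile 88.1, between the limits set. A regional difference and one of the gene itself cannot be told apart there. A strain variant carried by all mothers with the transgene would also be present in the rescued library. There, in progenitor-like cells, CG32368 lay near its control level, while CG31324 lay between the control and reprogrammed libraries, as given above. With 1 library per group, and the mothers' stocks not compared, this does not decide the question. A strain variant of each single gene, and an effect of the mothers' treatment, stay open as untested.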

How the results depend on the processing

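Alternatives were the settings named below. The share of the 3 named midgut classes, one mix of clusters in every library and the enteroendocrine-like cells without those with over 100 Akh UMIs were chosen after seeing the data. A list median counts as moved where it shifted by more than 0.5 of the width of the central 95% of random lists, and as having changed sign where the reported median lay outside that range and the other lies across 0. Without mitochondrial genes, the stricter cell filter acted on genes per cell alone. Lists left with too few measured members under a setting gave no value there. Of 2163 list medians under alternatives, 1930 stayed, 197 moved and 36 changed sign. Values that stayed include medians near 0 that crossed it. Of 1260 values of named genes, 845 stayed inside the counting interval of the reported ratio, 399 lay outside it, and 16 with an interval clear of 0 changed sign. The order of the progenitor-like shares, lowest in the control and highest in the rescued library, was kept under every alternative tried. Heat shock medians of rescued against control were negative in the 3 classes under every alternative. Depth limits the enteroendocrine-like class most, with 2.23, 1.79 and 1.19 M UMIs in the 3 libraries, so low genes there are the least certain. The cause of a moved value was not tested, except that one mix of clusters fixes the makeup of each class by construction, keeping doublets adds cells, and thinning leaves out shallow cells and most UMIs.

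Shares of kept cells stayed inside the reported interval in 65 of 135 values. Among cells with at least 500 genes per cell, the moved shares were progenitor-like 49.98%, 61.8% and 69.3%, enterocyte-like 12.3%, 9.13% and 11.9%, enteroendocrine-like 10.0% and 6.66% (reprogrammed and rescued), visceral muscle-like 3.60% and 1.52% (control and rescued), Malpighian tubule and hindgut-like 1.77%, 0.50% and 0.02%, hemocyte-like 0.63%, 0.87% and 1.03%, unnamed 17.3%, 13.9% and 9.24%. With no limit on genes per cell and predicted doublets still removed, the moved shares were progenitor-like 50.2% (control), enterocyte-like 21.5%, 15.9% and 19.96%, visceral muscle-like 5.32% (control), Malpighian tubule and hindgut-like 0.00%, 0.00% and 0.00%, unnamed 10.7%, 7.10% and 5.12%. With predicted doublets kept, the moved shares were progenitor-like 52.5%, 62.1% and 66.5%, enterocyte-like 17.3% and 11.6% (control and reprogrammed), unnamed 9.41%, 7.80% and 6.86%. At Leiden resolution 0.5, the moved shares were progenitor-like 52.5%, 62.4% and 67.3%, hemocyte-like 0.74% and 0.81% (control and reprogrammed), unnamed 6.49%, 6.98% and 5.93%. At Leiden resolution 2.0, the moved shares were enterocyte-like 20.6%, 14.2% and 17.4%, Malpighian tubule and hindgut-like 1.56%, 0.27% and 0.05%, unnamed 13.6% and 7.22% (control and rescued). With stress genes and enzymes left out of the variable genes, the moved shares were progenitor-like 51.8%, 62.0% and 66.8%, hemocyte-like 0.81% (reprogrammed), unnamed 9.07%, 7.44% and 6.63%. As a share of the 3 named midgut classes only, the moved shares were progenitor-like 60.4%, 69.9% and 73.4%, enterocyte-like 23.9%, 15.1% and 17.4%, enteroendocrine-like 15.7%, 15.0% and 9.17%.

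The ratio of the rescued to the reprogrammed distance from control, reported as 1.23 (progenitor-like), 1.25 (enterocyte-like) and 1.39 (enteroendocrine-like), stayed in 6 of 25 values, moved in 18 and crossed 1 in 1, the enteroendocrine-like ratio with predicted doublets kept. With each cell thinned to 1000 UMIs, it was 1.12 (progenitor-like), 1.39 (enterocyte-like) and 1.49 (enteroendocrine-like). With predicted doublets kept, it was 1.48 (progenitor-like), 1.37 (enterocyte-like) and 0.87 (enteroendocrine-like). Among cells with at least 500 genes per cell, it was 1.18 (progenitor-like), 1.38 (enterocyte-like) and 1.08 (enteroendocrine-like). With one mix of clusters in every library, it was 1.25 (progenitor-like) and 1.32 (enterocyte-like). Over genes with at least 1000 UMIs, it was 1.06 (progenitor-like), 1.44 (enterocyte-like) and 3.49 (enteroendocrine-like). With median-of-ratios scaling, it was 1.35 (enterocyte-like). With a total without the 20 most abundant genes, it was 1.28 (enterocyte-like). With mean of CPM per cell, it was 1.14 (enterocyte-like) and 1.23 (enteroendocrine-like). Without the cells with over 100 Akh UMIs, it was 1.10 (enteroendocrine-like). The share of the selected genes' ratio that remained in the rescued library, reported as 58.9%, 79.2% and 75.8%, moved in 8 of 24 values, among them 2 with genes chosen on rescued against control, which measure another quantity. The enterocyte-like share was 57.4% with cells thinned to 1000 UMIs and 112% with predicted doublets kept. It was 121% under at least 500 genes per cell and 64.1% with 200 genes each way. The enteroendocrine-like share was 111% with cells thinned and 32.8% with predicted doublets kept. With genes chosen on rescued against control, the reprogrammed library had 29.3% (enterocyte-like) and 50.6% (enteroendocrine-like) of the rescued ratio, the roles being swapped by construction.

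Named genes changed sign as follows, with the reported log2 ratio in brackets. Among cells with at least 500 genes per cell, enteroendocrine-like noe was 0.97 for reprogrammed against control (-2.50). For rescued against reprogrammed, ImpL2 was -0.46 (8.69) and noe -2.17 (2.98) there. For rescued against control, Dl was 0.32 there (-0.73). With predicted doublets kept, enteroendocrine-like Dl was 1.01 (-0.70) and pros -0.33 (0.097) for reprogrammed against control. For rescued against reprogrammed, ImpL2 was -1.18 (8.69) and noe -2.001 (2.98) there. For rescued against control, ImpL2 was -0.41 (8.62) and Dl 0.46 (-0.73) there. With mean of CPM per cell, foxo was -0.081 in enterocyte-like cells, rescued against reprogrammed (0.25) and foxo was -0.13 in enterocyte-like cells, rescued against control (0.21). With each cell thinned to 1000 UMIs, foxo was -0.49 in enterocyte-like cells, rescued against reprogrammed (0.25), foxo was -0.39 in enterocyte-like cells, rescued against control (0.21) and Dl was 0.039 in enteroendocrine-like cells, rescued against control (-0.73). With one mix of clusters in every library, esg was -0.055 in progenitor-like cells, rescued against control (0.057).

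In the following, each value under the setting is followed by the reported value in brackets, and lists are named in short. With one mix of clusters in every library, 31 list medians moved and 8 changed sign. Lipid metabolism 0.035 (-0.12), ribosomal proteins -0.011 (0.12) and peptide hormones 0.056 (-0.14) changed sign in enterocyte-like cells, reprogrammed against control. Proteases -0.17 (0.23), carbohydrases -0.13 (0.42), cell cycle 0.028 (-0.22) and autophagy -0.041 (0.038) changed sign in progenitor-like cells, rescued against reprogrammed. Peptide hormones -0.014 (0.098) changed sign in enteroendocrine-like cells, rescued against reprogrammed. Complex I -0.16 (-0.085), complexes II-V -0.19 (-0.10), EGFR -0.14 (0.039), proteasome -0.19 (-0.083), carbohydrases -1.48 (-1.82), cell cycle -0.20 (0.073) and peptide hormones 0.35 (0.68) moved in progenitor-like cells, reprogrammed against control. Complex I -0.080 (0.057), complexes II-V -0.19 (-0.060), IMD immunity 0.39 (0.13), proteases 0.22 (-0.042), carbohydrases -0.37 (-0.63) and cell cycle 0.48 (0.86) moved in enterocyte-like cells, reprogrammed against control. Complex I -0.045 (-0.22), complexes II-V -0.14 (-0.32), tricarboxylic acid cycle 0.11 (-0.051), methionine metabolism 0.14 (-0.11), redox -0.028 (-0.23), unfolded protein response 0.13 (-0.046) and proteasome 0.074 (-0.14) moved in progenitor-like cells, rescued against reprogrammed. Polycomb 0.079 (-0.25), heat shock -1.89 (-2.27), ribosomal proteins -0.002 (-0.15), carbohydrases 0.74 (1.01) and cell cycle -0.23 (-0.83) moved in enterocyte-like cells, rescued against reprogrammed. Ribosomal proteins -0.15 (-0.21) moved in enteroendocrine-like cells, rescued against reprogrammed. Complex I -0.18 (-0.28), methionine metabolism 0.003 (-0.15), proteasome -0.091 (-0.22) and carbohydrases -1.30 (-1.05) moved in progenitor-like cells, rescued against control. Carbohydrases 0.40 (0.82) moved in enterocyte-like cells, rescued against control.

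With each cell thinned to 1000 UMIs, 50 list medians moved and 6 changed sign. Peptide hormones 0.39 (-0.14) and autophagy 0.084 (-0.078) changed sign in enterocyte-like cells, reprogrammed against control. Proteases -0.041 (0.23) changed sign in progenitor-like cells, rescued against reprogrammed. Proteases -0.004 (0.12) changed sign in enterocyte-like cells, rescued against reprogrammed. Septate junctions -0.071 (0.12) changed sign in progenitor-like cells, rescued against control. Methionine metabolism -0.084 (0.43) changed sign in enterocyte-like cells, rescued against control. Insulin/TOR/FOXO 0.11 (-0.011), IMD immunity -0.046 (-0.25), EGFR -0.13 (0.039), heat shock -0.64 (-0.43), carbohydrases -2.18 (-1.82), metal handling -0.18 (0.007) and peptide hormones 0.090 (0.68) moved in progenitor-like cells, reprogrammed against control. Insulin/TOR/FOXO -0.33 (0.099), EGFR 0.94 (0.31), unfolded protein response -0.14 (0.19) and carbohydrases -0.35 (-0.63) moved in enterocyte-like cells, reprogrammed against control. Trithorax and demethylases 0.21 (-0.020), JNK 0.19 (-0.16), heat shock -0.71 (-0.56), proteasome 0.12 (0.021), ribosomal proteins -0.023 (0.065), carbohydrases -1.68 (-2.23), metal handling 0.33 (0.11) and peptide hormones 0.27 (0.14) moved in enteroendocrine-like cells, reprogrammed against control. JAK-STAT 0.044 (-0.19), heat shock -1.39 (-1.22) and septate junctions 0.092 (0.23) moved in progenitor-like cells, rescued against reprogrammed. Methionine metabolism -0.28 (0.058), insulin/TOR/FOXO -0.27 (0.007), IMD immunity -0.60 (-0.14), heat shock -1.59 (-2.27), metal handling -0.60 (-0.087) and peptide hormones -0.50 (-0.13) moved in enterocyte-like cells, rescued against reprogrammed. Complexes II-V -0.17 (-0.30), insulin/TOR/FOXO -0.30 (-0.069), proteases 0.26 (-0.018) and metal handling -0.36 (-0.11) moved in enteroendocrine-like cells, rescued against reprogrammed. Tricarboxylic acid cycle -0.36 (-0.20), heat shock -1.98 (-1.58), unfolded protein response -0.089 (0.042), carbohydrases -1.33 (-1.05), metal handling -0.19 (0.031), cell cycle -0.29 (-0.18) and peptide hormones 0.046 (-0.33) moved in progenitor-like cells, rescued against control. Insulin/TOR/FOXO -0.60 (0.10), EGFR 0.38 (-0.11), heat shock -2.04 (-3.01), proteases 0.040 (0.27) and metal handling -0.35 (-0.030) moved in enterocyte-like cells, rescued against control. Complexes II-V -0.31 (-0.48), heat shock -2.26 (-1.77), ribosomal proteins -0.24 (-0.13), proteases -1.24 (-1.51), carbohydrases -0.27 (-1.35) and septate junctions 0.61 (0.18) moved in enteroendocrine-like cells, rescued against control.

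With mean of CPM per cell, 24 list medians moved and 7 changed sign. Lipid metabolism 0.036 (-0.12), peptide hormones 0.45 (-0.14) and autophagy 0.17 (-0.078) changed sign in enterocyte-like cells, reprogrammed against control. Notch -0.076 (0.31) changed sign in enteroendocrine-like cells, reprogrammed against control. Proteases -0.089 (0.12) changed sign in enterocyte-like cells, rescued against reprogrammed. Peptide hormones -0.11 (0.098) changed sign in enteroendocrine-like cells, rescued against reprogrammed. Cell cycle 0.21 (-0.72) changed sign in enteroendocrine-like cells, rescued against control. EGFR -0.13 (0.039), heat shock -0.56 (-0.43), cell cycle -0.027 (0.073) and peptide hormones 0.27 (0.68) moved in progenitor-like cells, reprogrammed against control. Insulin/TOR/FOXO 0.31 (0.099), JAK-STAT 0.52 (0.037) and carbohydrases -0.33 (-0.63) moved in enterocyte-like cells, reprogrammed against control. Trithorax and demethylases 0.23 (-0.020), heat shock -0.72 (-0.56), ribosomal proteins -0.048 (0.065), metal handling 0.31 (0.11) and peptide hormones 0.26 (0.14) moved in enteroendocrine-like cells, reprogrammed against control. Heat shock -1.06 (-1.22) and peptide hormones -1.67 (-1.12) moved in progenitor-like cells, rescued against reprogrammed. Complex I -0.10 (-0.27), heat shock -1.37 (-1.10) and cell cycle -0.32 (-1.02) moved in enteroendocrine-like cells, rescued against reprogrammed. Proteases -1.76 (-1.62), metal handling -0.17 (0.031) and peptide hormones -0.68 (-0.33) moved in progenitor-like cells, rescued against control. Heat shock -2.34 (-3.01), proteases 0.003 (0.27) and peptide hormones 0.18 (-0.19) moved in enterocyte-like cells, rescued against control. Ribosomal proteins -0.27 (-0.13) moved in enteroendocrine-like cells, rescued against control.

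With predicted doublets kept, 34 list medians moved and 7 changed sign. Ribosomal proteins -0.010 (0.12) changed sign in enterocyte-like cells, reprogrammed against control. Septate junctions -0.081 (0.29) and peptide hormones -0.23 (0.14) changed sign in enteroendocrine-like cells, reprogrammed against control. Proteases -0.47 (0.23) changed sign in progenitor-like cells, rescued against reprogrammed. Proteases -0.097 (0.12) changed sign in enterocyte-like cells, rescued against reprogrammed. Tricarboxylic acid cycle 0.023 (-0.28) and cell cycle 0.16 (-0.72) changed sign in enteroendocrine-like cells, rescued against control. Proteases -0.88 (-1.64), carbohydrases -1.34 (-1.82) and peptide hormones 0.40 (0.68) moved in progenitor-like cells, reprogrammed against control. Heat shock -0.55 (-0.19), proteases 0.083 (-0.042) and cell cycle 0.56 (0.86) moved in enterocyte-like cells, reprogrammed against control. Notch 0.99 (0.31), EGFR 0.38 (0.16), redox -0.23 (0.010), unfolded protein response -0.093 (0.047), ribosomal proteins 0.29 (0.065), proteases -1.75 (-1.39), metal handling -0.21 (0.11), proton pump -0.22 (-0.024), cell cycle 0.60 (-0.23) and autophagy -0.18 (0.007) moved in enteroendocrine-like cells, reprogrammed against control. Carbohydrases 0.097 (0.42) moved in progenitor-like cells, rescued against reprogrammed. Polycomb 0.16 (-0.25), EGFR -0.18 (-0.53), ribosomal proteins 0.026 (-0.15) and cell cycle -0.49 (-0.83) moved in enterocyte-like cells, rescued against reprogrammed. Complex I -0.11 (-0.27), redox -0.008 (-0.19), proteases 1.13 (-0.018), carbohydrases 1.34 (0.45), metal handling 0.22 (-0.11) and peptide hormones 0.29 (0.098) moved in enteroendocrine-like cells, rescued against reprogrammed. Peptide hormones -0.002 (-0.33) and sex and dosage -1.18 (-0.21) moved in progenitor-like cells, rescued against control. Complexes II-V -0.33 (-0.48), Notch 0.46 (-0.009), ribosomal proteins 0.038 (-0.13), proteases -0.71 (-1.51) and carbohydrases -0.21 (-1.35) moved in enteroendocrine-like cells, rescued against control.

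Over members with at least 200 UMIs, 12 list medians moved and 2 changed sign. Carbohydrases 0.090 (-2.23) changed sign in enteroendocrine-like cells, reprogrammed against control. Carbohydrases 0.30 (-1.35) changed sign in enteroendocrine-like cells, rescued against control. Carbohydrases -2.56 (-1.82) moved in progenitor-like cells, reprogrammed against control. Trithorax and demethylases 0.31 (-0.020) moved in enteroendocrine-like cells, reprogrammed against control. Carbohydrases 0.80 (0.42) moved in progenitor-like cells, rescued against reprogrammed. Heat shock -1.47 (-2.27) moved in enterocyte-like cells, rescued against reprogrammed. Insulin/TOR/FOXO -0.33 (-0.069) and heat shock -1.48 (-1.10) moved in enteroendocrine-like cells, rescued against reprogrammed. Heat shock -1.78 (-1.58) and carbohydrases -1.94 (-1.05) moved in progenitor-like cells, rescued against control. Insulin/TOR/FOXO -0.31 (0.10) and heat shock -2.52 (-3.01) moved in enterocyte-like cells, rescued against control. Heat shock -1.98 (-1.77) and septate junctions 0.50 (0.18) moved in enteroendocrine-like cells, rescued against control.

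Among cells with at least 500 genes per cell, 23 list medians moved and 5 changed sign. Peptide hormones -0.13 (0.68) changed sign in progenitor-like cells, reprogrammed against control. Ribosomal proteins -0.016 (0.12) changed sign in enterocyte-like cells, reprogrammed against control. Proteases -0.064 (0.12) changed sign in enterocyte-like cells, rescued against reprogrammed. Peptide hormones -0.12 (0.098) changed sign in enteroendocrine-like cells, rescued against reprogrammed. Peptide hormones -0.004 (0.15) changed sign in enteroendocrine-like cells, rescued against control. Complexes II-V -0.16 (-0.060), heat shock -0.56 (-0.19), proteases 0.096 (-0.042) and cell cycle 0.34 (0.86) moved in enterocyte-like cells, reprogrammed against control. Complexes II-V -0.066 (-0.13), Notch 0.009 (0.31), heat shock -0.69 (-0.56), proteasome 0.14 (0.021), proteases -1.68 (-1.39) and cell cycle 0.59 (-0.23) moved in enteroendocrine-like cells, reprogrammed against control. Peptide hormones -0.78 (-1.12) moved in progenitor-like cells, rescued against reprogrammed. Polycomb 0.13 (-0.25), EGFR -0.16 (-0.53) and ribosomal proteins 0.039 (-0.15) moved in enterocyte-like cells, rescued against reprogrammed. Notch 0.48 (-0.15) and ribosomal proteins -0.003 (-0.21) moved in enteroendocrine-like cells, rescued against reprogrammed. Carbohydrases -1.38 (-1.05), peptide hormones -1.51 (-0.33) and sex and dosage -1.29 (-0.21) moved in progenitor-like cells, rescued against control. Heat shock -2.59 (-3.01) moved in enterocyte-like cells, rescued against control. Tricarboxylic acid cycle -0.025 (-0.28), Notch 0.41 (-0.009) and ribosomal proteins 0.054 (-0.13) moved in enteroendocrine-like cells, rescued against control.

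Over members with at least 10 UMIs, 8 list medians moved and 0 changed sign. Peptide hormones 0.39 (0.68) moved in progenitor-like cells, reprogrammed against control. Carbohydrases 0.93 (0.45), septate junctions -0.11 (0.17) and cell cycle -0.23 (-1.02) moved in enteroendocrine-like cells, rescued against reprogrammed. Heat shock -1.78 (-1.58) and carbohydrases -0.77 (-1.05) moved in progenitor-like cells, rescued against control. Lipid metabolism 0.19 (-0.24) moved in enterocyte-like cells, rescued against control. Carbohydrases -0.27 (-1.35) moved in enteroendocrine-like cells, rescued against control.

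With median-of-ratios scaling, 12 list medians moved and 1 changed sign. Ribosomal proteins -0.078 (0.12) changed sign in enterocyte-like cells, reprogrammed against control. Complex I -0.14 (0.057), complexes II-V -0.25 (-0.060), redox -0.45 (-0.26), proteasome 0.17 (0.36), proteases -0.23 (-0.042), carbohydrases -0.82 (-0.63) and proton pump -0.52 (-0.32) moved in enterocyte-like cells, reprogrammed against control. Ribosomal proteins 0.038 (0.065) moved in enteroendocrine-like cells, reprogrammed against control. Ribosomal proteins 0.13 (0.073) moved in progenitor-like cells, rescued against reprogrammed. Complexes II-V -0.41 (-0.60), ribosomal proteins 0.046 (-0.15) and proteases 0.31 (0.12) moved in enterocyte-like cells, rescued against reprogrammed.

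With a total without the 20 most abundant genes, 3 list medians moved and 0 changed sign. Ribosomal proteins -0.059 (-0.15) moved in enterocyte-like cells, rescued against reprogrammed. Ribosomal proteins -0.13 (-0.21) moved in enteroendocrine-like cells, rescued against reprogrammed. Ribosomal proteins -0.068 (-0.13) moved in enteroendocrine-like cells, rescued against control.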

Other observations

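Visceral muscle-like cells, which the comparisons leave out, were 267, 207 and 107 cells in the control, reprogrammed and rescued libraries. For reprogrammed against control, 31 of 31 proteasome genes were higher (median log2 ratio 0.48, with a median of 0.27 over all genes), 32 of 33 genes of respiratory complexes II to V were lower (-0.33), and 8 of 10 EGFR pathway genes were higher (0.70). Genes of other cell types differed as well: peptide hormones were lower in 4 of 4 (-6.76) and digestive proteases in 8 of 8 (-2.01), and in rescued against control these medians were -6.46 and -1.97. Whether the makeup of these cells, or the free RNA in them, was alike in the libraries was not tested. For rescued against control, 31 of 31 proteasome genes were higher (0.56, all genes 0.17) and 33 of 33 complex II to V genes lower (-0.50). Hsp26 stood at 866.7, 1336.0 and 301.6 CPM in these cells. The unnamed cluster 5, led by CG8661, CG5767 and CG18404 and with raised enterocyte and copper cell markers, held 317, 250 and 302 cells. In it the 6 measured Notch pathway genes were higher in reprogrammed against control (median 2.07) and lower in rescued against reprogrammed (-1.78). Peptide hormones were higher in reprogrammed against control (7 of 9, 1.29) and lower in rescued against reprogrammed (7 of 9, -0.31), and carbohydrases (-0.99) and digestive proteases (-0.73) were lower in reprogrammed against control, and the makeup of the cluster was not held equal. Respiratory complexes II to V were lower in 33 of 33 in reprogrammed against control (-0.38) and in rescued against control (-0.77), and heat shock genes stood at -0.52 and -2.31 in these comparisons.

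Several genes with high counts over all kept cells came from few cells. CG34212, CG16826 and CG45080 had 13341, 12548 and 7705 UMIs in the rescued library, where 8 cells each held over 100, with the top cell in the cluster with Malpighian tubule and hindgut markers. They had 0 UMIs in the control library and 3, 0 and 0 in the reprogrammed library. Cpr49Ae had 3006, 83 and 63 UMIs and Obp99c 3434, 137 and 554 in the control, reprogrammed and rescued libraries, and 2 control cells held 86.2% of the Obp99c UMIs. The dosage compensation RNAs roX1 and roX2 had 36, 45 and 27 and 11, 10 and 9 UMIs. No further hypothesis was tested.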
